A study of Homo sapiens with 12 samples.

How the data were processed

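RNA labelled for 1 h with 0.5 mM 5-ethynyl uridine was measured in 12 libraries of MCF-7 cells, 3 for each combination of line (GFP or MYC-GFP) and treatment (untreated or 400 ng/mL NCS). Per the labels' protocols, 150 ng of labelled S. pombe RNA was added for a fixed number of cells, with cell numbers counted on other plates of the same line and treatment, labelled RNA was captured by click chemistry, cDNA was made with a template-switching kit and 6 cycles of PCR, and libraries were made by tagmentation. Reads were aligned with TopHat2 2.1.0 and handled in Partek on the human hg19 and S. pombe ASM294v2 builds, per the submitters' processing notes, which do not say how reads were counted or whether strand was used. The deposited human and S. pombe tables hold estimated counts of reads per transcript, per the file headers, not scaled for depth or length. Of their values 10.3% and 23.0% were not whole within a tolerance of 0.01. A further deposited table is named as normalised to S. pombe, but each of its 186124 nonzero values was the read count divided by the transcript length in kilobases (relative tolerance 1e-09), that is reads per kilobase without spike-in scaling. The authors also deposited 1 S. pombe score per library, per the file headers, without its formula. Every column of values was matched to a sample (0 unmatched), and no mitochondrial gene was in the human table.

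The human table listed 18532 transcripts with 18458 gene symbols, and reads of the 64 symbols on more than 1 line were summed. The S. pombe table listed 6363 transcripts. Depth was 4804502 to 8363431 human and 79421 to 113592 S. pombe reads per library. Positions are those of the human table, on hg19. The ratio of human to S. pombe reads was compared on the log2 scale with exact 2-sided permutation tests: 20 arrangements for 3 against 3 libraries, where the smallest p is 0.1, 400 for a factor stratified by the other, and all splits of the residuals for the interaction.

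Genes were tested with edgeR 4.0.16 in R 4.3.3. The estimated counts were summed per gene, rounded to whole numbers and passed through filterByExpr with default settings, which left 12858 genes, then estimateDisp, robust glmQLFit and glmQLFTest on a model of the 4 group means (8 residual degrees of freedom, common biological coefficient of variation 0.264). Adjusted p values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and genes under 0.05 were called. Library sizes were either human totals with TMM factors, which gives changes relative to the typical gene, or S. pombe totals, which gives changes per S. pombe read. CPM values use the TMM factors. The standard error of a log2 change is its size divided by the square root of the test's F value. The 24 gene lists, 3 of them markers of other cell types, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a contrast. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move 1 way and not whether they differ from other genes. The mitochondrial list had no measured member and gave no result, so 23 were tested. A few lists share genes, at most 3 for any pair. Camera was run on the relative scale only.

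Genes named in the text followed a rule. MYC, TP53, CDKN1A and MDM2 were always read. For each contrast, the 8 largest rises and 8 largest falls came from called genes with a mean of at least 5 CPM and no overlap between the groups. From each described list came up to 4 members with the smallest p, and for the interaction the 5 genes with the smallest p. Lists, tests, the named-gene rule and most alternatives were fixed before the data were examined. Genes shown for chromosome windows were chosen after their values were seen. A result that names an item withheld for evaluation was left out. Where a group had 0 reads of a gene, the fold is a bound from a floor of 3 counts over the group. With 1 to 3 reads it is a ratio with a 95% exact interval. Both cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

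Shares of reads from short and long transcripts used quartiles of transcript length (at most 1693 and over 4302 bases for human, at most 1161 and over 2554 for S. pombe). Chromosome windows of 25 neighbouring tested genes were compared with 1000 random gene orders. Same-numbered libraries deviated from their group means together, with each r above 0.1, for the untreated lines (0.199, 0.429 and 0.507) and for the MYC-GFP line with and without NCS (0.178, 0.131 and 0.434). They did not for the other 4 pairs of groups, so no block entered the model. Alternatives were DESeq2 1.42.0, other scalings and filters, limma on log2 values with pseudocounts 1 and 0.1, and fits of 2 groups only. Others were counts per transcript in place of sums per gene, a replicate block, leaving out each library in turn, and fits without 3 or 4 of the libraries numbered 3. The list of MYC-repressed genes was also tested without the members it shares with p53 targets. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

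The tests were checked on simulated counts with known changes. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery among genes of fewer reads was not checked. For NCS in the GFP line (12684 genes run) the tests recovered 1.49%, 16.4% and 95.5% of genes changed 1.5-, 2- and 4-fold. The shares were 1.49%, 23.9% and 93.9% for NCS in the MYC-GFP line (12668 genes) and 0%, 31.3% and 93.9% for the lines untreated (12674 genes). They were 1.49%, 19.4% and 97% for the lines with NCS (12662 genes) and 1.49%, 4.48% and 60.6% for the interaction (12672 genes), with 1 to 5 of 12658 unchanged genes called. For NCS in the GFP line, a list raised 1.5-fold was called with both correlations and 0 of the other lists were called. The simulated genes were drawn independently, with no difference in transcript length between libraries. These checks therefore say nothing about false calls from correlated genes or from such differences in the real libraries. For the chromosome windows, p was 0.001 with 10 shifted windows and 0.9 with none.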

Results

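Newly made RNA was measured in MCF-7 cells, an established human breast carcinoma line, with or without DNA double-strand breaks and with or without an inducible MYC construct. Clonal lines carrying doxycycline-inducible GFP or MYC-GFP received 150 ng/mL doxycycline for 18 h and then either no further treatment or 400 ng/mL neocarzinostatin (NCS), a drug that breaks both DNA strands. RNA made from 2.5 to 3.5 h after treatment was labelled with 5-ethynyl uridine, captured and sequenced, with labelled RNA of the fission yeast Schizosaccharomyces pombe added in proportion to cell number. Each of the 4 groups had 3 libraries from separate plates. The libraries held 4804502 to 8363431 human reads and 79421 to 113592 S. pombe reads. Folds are relative to the typical gene unless they are given per S. pombe read, expression is in CPM (counts scaled to library size), and coordinates are on hg19.

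The first question was how much RNA the cells made per cell after breaks and with the MYC construct. Over both lines, human reads per S. pombe read were 24.6% lower with NCS than without (log2 -0.41, 2-sided exact permutation p = 0.025 over 400 arrangements). In the GFP line the mean was 73.4 ± 16.3 (SD, n = 3) untreated and 53.1 ± 4.89 with NCS, a log2 difference of -0.45 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). In the MYC-GFP line it was 85.9 ± 19.4 untreated and 65.6 ± 3.82 with NCS (log2 -0.37, exact permutation p = 0.3). Over both treatments the MYC-GFP line lay 20.2% above the GFP line (log2 0.27, exact permutation p = 0.085, but 0.35 and 0.035 without untreated GFP replicate 3 and 0.35 and 0.03 without untreated MYC-GFP replicate 2), with 16.9% in untreated cells (exact permutation p = 0.5) and 23.7% in NCS-treated cells (exact permutation p = 0.1). The difference of the NCS change between the lines was 0.08 on the log2 scale (exact permutation p = 0.753 over all arrangements of the residuals), and -0.080 or -0.090 without those libraries. With a replicate block p was 0.0313 for the lines over both treatments and 0.0625 for NCS over both lines (exact permutation), but same-numbered libraries deviated together in only 2 of 6 pairs of groups. In those 2, the untreated lines differed by 0.25, 0.21 and 0.22 within numbers (exact permutation p = 0.25 with the block, the smallest that 3 pairs allow), and NCS changed the MYC-GFP line by -0.49, 0.019 and -0.63 (exact permutation p = 0.5). The S. pombe amount followed cell counts from other plates, so an error in a count was shared by the 3 libraries of a group and is not covered by these p values. Library composition also differed within groups: transcripts of at most 1693 bases took 35.3% of human reads in replicate 3 of the untreated GFP line and 20.4 to 27.5% in the other libraries. On the log2 scale the NCS change over both lines was -0.55 for the shortest quartile of transcripts (exact permutation p = 0.06) and -0.19 for the longest (exact permutation p = 0.06), and without replicate 3 of untreated GFP, untreated MYC-GFP and NCS-treated MYC-GFP, each the highest of its group in that share, it was -0.26 (exact permutation p = 0.0833). Without replicate 3 of all 4 groups, that of NCS-treated GFP being the lowest of its group, it was -0.22 (exact permutation p = 0.167).

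**Figure D1:**
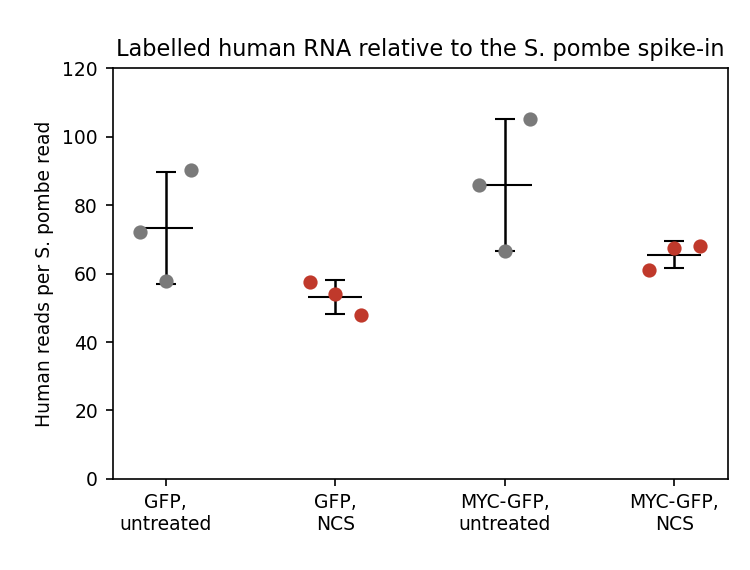
Human reads per S. pombe read in each library (points) with the group mean and SD (n = 3). The means were 73.4, 53.1, 85.9 and 65.6 for GFP untreated, GFP NCS, MYC-GFP untreated and MYC-GFP NCS, and untreated libraries spread more than NCS-treated ones.

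The next comparison asked which genes changed their transcription after breaks in the GFP line. Direct targets of p53, the transcription factor that DNA breaks activate, rose and mitotic genes fell. FAS, a death receptor (chromosome 10, 90750316 to 90776818), went from 9.74 ± 2.52 to 150.5 ± 25.2 CPM (n = 3 each), a log2 change of 3.95 with a standard error of 0.29 (adjusted p = 5.85e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36644237 to 36655116), rose 10.5-fold, from 206 ± 41.7 to 2160 ± 306 CPM (edgeR adjusted p = 5.85e-06), and MDM2, the ubiquitin ligase that limits p53, rose 9.27-fold from 270.5 ± 180 to 2506 ± 768 CPM (log2 3.21, and 3.82 without untreated replicate 2, edgeR adjusted p = 0.00356). The mitotic kinase gene AURKA fell from 271 ± 8.67 to 95.7 ± 13.5 CPM, a log2 change of -1.50 with a standard error of 0.17 (edgeR adjusted p = 0.000238), and PLK1, another mitotic kinase gene, was 3.32-fold lower (edgeR adjusted p = 0.00371). TP53 itself was not called changed (log2 0.11, edgeR adjusted p = 0.904, and log2 -0.25 without untreated replicate 3), and MYC was 1.87-fold lower without passing the threshold (697 ± 211 to 373 ± 46.4 CPM, edgeR adjusted p = 0.0716), and passed it without untreated replicate 3 (log2 -1.13, 0.00134). Per S. pombe read MYC was called lower (log2 -1.35, edgeR adjusted p = 0.0245), but not without untreated replicate 1 (0.157) or any 1 NCS-treated replicate (0.117 to 0.167).

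Of 12858 genes tested in the GFP line, 138 rose and 19 fell relative to the typical gene (edgeR, adjusted p under 0.05). The largest rises included SERPINB5, a serpin of epithelial cells (log2 4.01), ABCA12, a lipid transporter (3.42), TNFRSF10C, a decoy receptor for the death ligand TRAIL (3.29), ZNF488, a zinc finger gene (3.28), and FAM212B (3.18). Among p53 targets, SESN1, a stress-induced restraint on growth signalling, rose by 3.12 and GADD45A, a growth arrest gene, by 2.68. The helicase gene PIF1 fell by 2.70 on the log2 scale and the mitotic kinesin gene KIF20A fell by 1.53. The calls of all genes named so far as rising or falling held when each library was left out in turn, while CCNB1, the mitotic cyclin gene, at -1.41 (edgeR adjusted p = 0.0197), lost its call without each NCS-treated GFP replicate (0.0543, 0.0729 and 0.116 without replicates 1, 2 and 3). Per S. pombe read, where the typical gene shifted by -0.46, 45 genes rose and 27 fell, 61 of the 72 also being called on the relative scale, and 85.3% of all genes had a lower estimate after NCS. The relative count was 96 and 94 without NCS-treated replicates 1 and 2, and 90 and 253 without untreated replicates 1 and 2. The count per S. pombe read was 31 to 41 without NCS-treated replicates 1, 2 or 3 or untreated replicate 1, and 3199 (3073 of them lower) without untreated replicate 2.

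Among gene lists fixed beforehand, p53 targets had a median log2 change of 1.81 after NCS in the GFP line: 37 of 48 rose and 0 fell (45 and 0 adjusted over the list alone, camera adjusted p = 9e-158). G2/M genes had a median of -0.71, with 8 of 38 called lower (26 adjusted over the list alone, camera adjusted p = 8.88e-27). Ribosome biogenesis genes also lay low (median -0.44, camera adjusted p = 2.82e-07): DKC1, the pseudouridine synthase of ribosomal RNA, was the only 1 of 40 past the threshold (2 adjusted over the list alone), at -1.09 (edgeR adjusted p = 0.0416), and its call ended without any library of these groups other than untreated replicate 2 (edgeR adjusted p 0.0739 to 0.212). NF-kB targets (median 0.75, camera adjusted p = 1.98e-07, 2 of 18 called and 7 adjusted over the list alone) and G1/S genes (-0.41, 5.16e-05, 1 higher and 4 lower adjusted over the list alone) kept their calls with an estimated correlation between genes, as did the first 3 lists. MYC-repressed genes were called higher (median 0.21, at -0.24 per S. pombe read, camera adjusted p = 0.000117, and 0.0257 with an estimated correlation). Their 2 called members of 21, CDKN1A and GADD45A, are also p53 targets, and without these the median was -0.013 and the camera adjusted p 0.536. Immediate early genes had a median of 0.45 (camera adjusted p = 1.84e-09, 5 of 25 rose and 7 adjusted over the list alone) but of 0.0093 per S. pombe read, with 1 called on that scale. Those called relative to the typical gene included the transcription factor genes ATF3 (log2 2.23, edgeR adjusted p = 6.87e-05), FOSL1 (1.81, 0.00376) and KLF4 (1.08, 0.0054). MYC targets in metabolism (median -0.33, camera adjusted p = 5.16e-05) and histones (0.27, 0.0377, at -0.13 per S. pombe read) were called too, but these and the immediate early list lost the call, with adjusted p = 0.132, 0.761 and 0.109 with an estimated correlation. The histone call also ended without untreated replicate 1 (0.169) or 3 (0.5) or NCS-treated replicate 3 (0.358).

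The other lists were not called in the GFP line, and per S. pombe read each of their medians was negative. The relative medians and camera adjusted p values were -0.04 and 0.87 for estrogen receptor targets, 0.10 and 0.88 for luminal identity, 0.02 and 0.943 for interferon-stimulated genes, and 0.10 and 0.87 for the integrated stress and unfolded protein response. They were -0.14 and 0.535 for heat shock genes, 0.03 and 0.87 for double-strand break repair, -0.09 and 0.617 for ribosomal proteins, -0.11 and 0.466 for sterol synthesis, and -0.23 and 0.46 for glycolysis and hypoxia. They were -0.08 and 0.666 for the RNA polymerase II machinery and 0.18 and 0.46 for snoRNA host genes. Markers of other cell types were sparse: 4 of 15 stromal (0.41 and 0.0563, fry adjusted p = 0.0236), 1 of 16 leukocyte (-0.71 and 0.535) and 8 of 12 basal genes (0.16 and 0.748) were measured. The stromal marker ACTA2 (chromosome 10, 90694831 to 90751154) rose 4.58-fold (edgeR adjusted p = 0.00376). A small part of its interval, at 1 end, overlaps FAS on the other strand, and no strand was stated for the counting. Reads in that part cannot be told from those of FAS, and their share in the rise was not tested. DDIT4, an mTOR inhibitor in the stress list, rose 3.85-fold (edgeR adjusted p = 0.00376).

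The same question was asked in cells labelled MYC-GFP. FAS went from 6.04 ± 2.18 to 116 ± 14.5 CPM (n = 3 each), a log2 change of 4.26 with a standard error of 0.29 (edgeR adjusted p = 4.97e-06). CDKN1A rose 6.79-fold, from 266 ± 66.1 to 1806 ± 330 CPM (edgeR adjusted p = 4.61e-05), and MDM2 rose 9.78-fold, from 277 ± 119 to 2708 ± 775 CPM (edgeR adjusted p = 0.00406). AURKA fell from 202 ± 14.3 to 95.2 ± 2.24 CPM, a log2 change of -1.09 (edgeR adjusted p = 0.0047), and CENPA, the centromeric histone gene, fell by 1.22 (edgeR adjusted p = 0.00307). MYC was 1.80-fold lower without passing the threshold (799 ± 39.4 to 443 ± 26.6 CPM, edgeR adjusted p = 0.152, and 0.0618 per S. pombe read), and TP53 was not called (log2 0.51, edgeR adjusted p = 0.574).

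In this line 77 genes rose and 10 fell relative to the typical gene (edgeR, adjusted p under 0.05). SERPINB5 rose by 3.74 on the log2 scale, SPATA18, a p53 target in mitochondrial quality control, by 3.57, EDA2R, a death receptor gene, by 3.05, and SESN1 by 2.92. PLK1 was 2.80-fold lower (edgeR adjusted p = 0.0162) but lost its call without untreated replicate 3 (0.087), NCS-treated replicate 1 (0.132) or NCS-treated replicate 2 (0.101), while every other gene named as rising or falling here kept its call without any 1 library. Per S. pombe read, where the typical gene shifted by -0.37, 33 genes rose and 12 fell, 43 of the 45 being called on both scales, and 78.3% of genes had a lower estimate. The relative count was 52 and 51 without NCS-treated replicates 1 and 2, and 56 without untreated replicate 2 or 3. The count per S. pombe read was 17 to 21 without any 1 NCS-treated replicate or untreated replicate 1, and 28 without untreated replicate 3.

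In the MYC-GFP line 32 of 48 p53 targets rose after NCS and 0 fell (44 and 0 adjusted over the list alone, median 1.76, camera adjusted p = 3.46e-139), ATF3 again among the early genes at 2.14 (edgeR adjusted p = 0.000151). G2/M genes had a median of -0.44 with 4 of 38 called lower (11 adjusted over the list alone, camera adjusted p = 6.31e-17). Ribosome biogenesis genes had a median of -0.30 (camera adjusted p = 0.000776, 0 called, DKC1 at -0.70) and NF-kB targets 0.46 (2.81e-05). Those 4 lists kept their calls with an estimated correlation. The other calls were lost: MYC targets in metabolism (median -0.24, adjusted p = 0.228 with an estimated correlation), G1/S genes (-0.17, 0.217), luminal identity (-0.27, 0.439), histones (0.51, 0.509) and MYC-repressed genes (0.07, 0.0766, at -0.28 per S. pombe read, and camera adjusted p = 0.857 without CDKN1A and GADD45A). The luminal call also ended without untreated replicate 2 (camera adjusted p = 0.0783) or 3 (0.125) or NCS-treated replicate 1 (0.118) or 2 (0.0964), and the histone call without untreated replicate 3 (0.166). Immediate early genes were not called in this line (median -0.05, camera adjusted p = 0.562).

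NCS calls overlapped between the lines. FAS, CDKN1A, MDM2, SESN1, GADD45A and SERPINB5 were among 66 genes that rose in both, against 0.826 expected for independent lists of 138 and 77. AURKA was among 9 that fell in both, against 0.0148 expected for lists of 19 and 10. No gene was called in opposite directions: 0 of the 75 shared genes, by edgeR. The shared count was 48 and 49 without NCS-treated MYC-GFP replicates 1 and 2. Across genes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.622.

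The other axis of the design compared the lines labelled GFP and MYC-GFP, so MYC RNA was read first in each library. Untreated GFP libraries held 846.8, 788.1 and 455.9 CPM of MYC (chromosome 8, 128748315 to 128753680) and untreated MYC-GFP libraries 753.4, 824 and 819.1 CPM. With NCS they held 327.4, 420.1 and 371.8 CPM in the GFP line and 472.2, 437.4 and 419.9 CPM in the line labelled MYC-GFP. The MYC-GFP line was 1.15-fold higher untreated (log2 0.20, standard error 0.22, edgeR adjusted p = 0.747), a difference of -0.060 without untreated GFP replicate 3. With NCS it was 1.19-fold higher (log2 0.25, edgeR adjusted p = 0.744). MYC was therefore not called higher in the libraries labelled MYC-GFP, and reads of the construct cannot be told from those of the endogenous gene in these counts.

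Between the untreated lines single genes differed by large factors. CTSD, the lysosomal protease cathepsin D (chromosome 11, 1773982 to 1785222), stood at 111 ± 45.9 CPM in the GFP line and 756 ± 243 CPM in the line labelled MYC-GFP (n = 3 each), 6.80-fold higher (log2 2.76, standard error 0.36, edgeR adjusted p = 0.000505). HOXB2, a homeobox transcription factor gene, was 10.8-fold higher (4.10 ± 0.667 to 44.6 ± 5.58 CPM, edgeR adjusted p = 8.68e-06), and the secreted mucin gene MUC5AC 10.4-fold higher (edgeR adjusted p = 0.000733). UGT1A6, a glucuronosyltransferase, was 31.3-fold lower (277 ± 39.0 to 8.81 ± 2.23 CPM, edgeR adjusted p = 1.19e-07), although it shares exons with the other UGT1A genes and the split of reads among them is uncertain. NCAM2, a neural cell adhesion gene, was 80.2-fold lower (edgeR adjusted p = 3.31e-07).

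Several genes were read almost only in 1 untreated line. BRINP3, a neural gene, had 3 reads in the GFP line and 702 in the MYC-GFP line, a log2 ratio of 7.90 with a 95% counting interval of 6.34 to 10.18. MALRD1 and PLXDC2 are neighbours on chromosome 10 (19337700 to 20023407 and 20105372 to 20578784). MALRD1 had 328 reads in the GFP line and 0 in the other, at least 107-fold lower from a floor of 3 counts over the group, and PLXDC2 had 246 and 1, a log2 ratio of -7.92 (95% interval -13.23 to -5.42). Also higher in the MYC-GFP line were TNIK, a signalling kinase (log2 3.75), MARCKS, a membrane-bound kinase substrate (3.31), NELFB, a subunit of the elongation-pausing complex (1.74), and MUC1, a membrane mucin (2.06). Lower were DSCAM, a cell adhesion gene (-5.82), and CAV1, the caveolin 1 gene (-1.37). Each of these calls held without any 1 library, but some folds moved by over 1.5 times: TNIK to 4.55 and 3.14 without GFP replicates 1 and 3, DSCAM to -6.83 and -5.19 without MYC-GFP replicates 2 and 3, BRINP3 to 8.60 without GFP replicate 2, and PLXDC2 to -9.16 without MYC-GFP replicate 1 (log2, edgeR). Over all such fits BRINP3 ranged from 7.15 to 8.60 and PLXDC2 from -9.16 to -6.91.

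In untreated cells 167 genes were higher and 256 lower in the line labelled MYC-GFP (edgeR, adjusted p under 0.05). Per S. pombe read, where the typical gene shifted by 0.17, 178 were higher and 156 lower, with 292 called on both scales. The relative count was 239 without GFP replicate 1 and 231, 212 and 270 without MYC-GFP replicates 1, 2 and 3, and the count per S. pombe read 193, 154 and 209 without GFP replicate 1 and MYC-GFP replicates 1 and 3. The 2 lists of MYC targets were not called: ribosome biogenesis had a median of -0.05 (0.12 per S. pombe read, camera adjusted p = 0.808) and MYC targets in metabolism 0.00 (0.17 per S. pombe read, camera adjusted p = 0.74), where the polyamine synthesis gene ODC1 alone was called (log2 0.73, edgeR adjusted p = 0.0331) and lost its call without any 1 of the 6 libraries (edgeR adjusted p 0.0567 to 0.185) or with a replicate block (0.058). NF-kB targets were called higher (median 0.52, camera adjusted p = 5.14e-05, 5 of 18 genes and 6 adjusted over the list alone), among them ICAM1, a leukocyte adhesion receptor (2.04), and BIRC3, an inhibitor of cell death (1.44). Sterol synthesis genes (median 0.35, camera adjusted p = 0.0042, 18 of 20 positive, 0 called), luminal identity (0.33, 0.0042) and immediate early genes (0.26, 0.0126) were called too. By fry the first 2 of these 4 were called (0.00249 each). All 4 calls were lost, with adjusted p = 0.0594 for NF-kB targets and sterol synthesis, 0.631 for luminal identity and 0.715 for immediate early genes with an estimated correlation, and the early-gene call also ended without GFP replicate 3 (0.4). p53 targets were not called (median 0.06, camera adjusted p = 0.74), with 3 of 48 lower (4 lower and 1 higher adjusted over the list alone): EDA2R (-1.29, edgeR adjusted p = 0.0344), FDXR (-1.61, 0.0446) and TP53I3 (-1.18, 0.045). Each lost its call without GFP replicate 1 or 3 or MYC-GFP replicate 1 or 2 (0.0603 to 0.199), and FDXR (0.0788) and TP53I3 (0.0753) also without MYC-GFP replicate 3 or with a replicate block (0.0571 and 0.0587). Of 8 measured basal and myoepithelial markers, 2 were called lower (list median -0.30, camera adjusted p = 0.526, fry adjusted p = 0.0125): CAV1 and OXTR, the oxytocin receptor gene (-1.58), which lost its call without GFP replicate 1 (0.0567) or MYC-GFP replicate 1 (0.068) or 2 (0.0707). Of 4 measured stromal markers (median -0.53, camera adjusted p = 0.647) the collagen gene COL3A1, named after its values were seen, was lower (-3.53, edgeR adjusted p = 0.0219), but not without GFP replicate 3 (0.0525) or any 1 MYC-GFP replicate (0.0557 to 0.099).

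**Figure D2:**
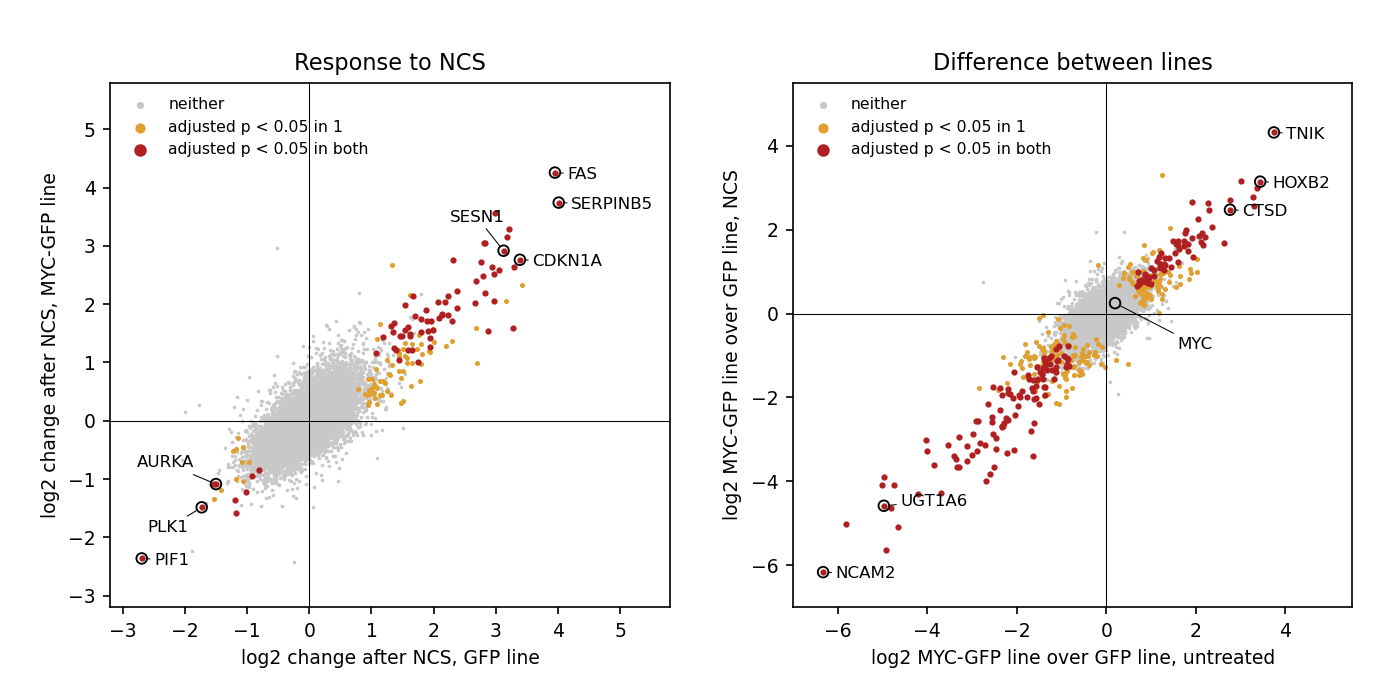
Log2 fold changes relative to the typical gene of the 10601 genes with a mean of at least 5 CPM and at least 0.2 CPM in each group, for NCS in the GFP line against the MYC-GFP line and for the MYC-GFP line against the GFP line in untreated against NCS-treated cells, with called genes coloured. p53 targets such as FAS and CDKN1A rose in both lines, and genes such as HOXB2 and UGT1A6 differed between the lines under both treatments.

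The same comparison of the lines was made after NCS. HOXB2 was 8.84-fold higher (4.13 ± 1.46 to 36.4 ± 3.40 CPM, n = 3 each, edgeR adjusted p = 1.96e-05), CTSD 5.56-fold higher (85.5 ± 19.4 to 475 ± 186 CPM, edgeR adjusted p = 0.00119) and MUC1 4.74-fold higher (edgeR adjusted p = 0.00105). CAV1 was 3.83-fold lower (143 ± 26.7 to 37.2 ± 6.91 CPM, edgeR adjusted p = 0.000311), the receptor gene OXTR 4.07-fold lower (edgeR adjusted p = 0.00324), the vasodilator peptide gene ADM 2.36-fold lower (edgeR adjusted p = 0.00177), and CDKN2B, a cyclin-dependent kinase inhibitor gene on the list of MYC-repressed genes, 2.67-fold lower (edgeR adjusted p = 0.00551). CDKN1A (log2 -0.26, edgeR adjusted p = 0.747), MDM2 (0.11, 0.964, with log2 -0.056 and -0.050 without replicate 2 of either line) and TP53 (-0.22, 0.872) were not called between the NCS-treated lines. MALRD1 was at least 62.2-fold lower (193 reads against 0) and PLXDC2 at least 86.7-fold lower (269 against 0).

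In NCS-treated cells 105 genes were higher and 243 lower in the line labelled MYC-GFP (edgeR, adjusted p under 0.05), and per S. pombe read, where the typical gene shifted by 0.26, 189 were higher and 127 lower, with 226 called on both scales. The relative count was 176 and 180 without GFP replicates 1 and 2, and 162, 178 and 218 without MYC-GFP replicates 1, 2 and 3. The count per S. pombe read was 126, 139 and 148 without GFP replicates 1, 2 and 3, and 120, 125 and 188 without the MYC-GFP replicates. Without the 3 libraries named for transcript length the counts were 782 and 869, and without replicate 3 of each group 2361 and 1268. In that last fit short transcripts took 25.5 and 27.3% of human reads in the GFP line and 20.4 and 20.8% in the MYC-GFP line. A difference between the lines cannot be told there from one of transcript length between libraries. G2/M genes were called higher (median 0.28, camera adjusted p = 0.000233, 34 of 38 positive, 0 called and 4 adjusted over the list alone), as were NF-kB targets (0.36, 0.00157) and sterol synthesis genes (0.34, 0.0049, 19 of 20 positive). All 3 calls were lost, with adjusted p = 0.069, 0.149 and 0.069 with an estimated correlation. Ribosome biogenesis genes (median 0.15, camera adjusted p = 0.121), MYC targets in metabolism (0.11, 0.299), MYC-repressed genes (-0.18 but 0.08 per S. pombe read, 0.172) and p53 targets (-0.21 but 0.05 per S. pombe read, 0.0513) were not called by camera, nor were basal (0.13, 0.26) or stromal markers (-0.67, 0.277), although CAV1 and OXTR were lower. By fry, ribosome biogenesis (0.0412), MYC-repressed genes (0.0483), p53 targets (0.022) and basal markers (0.0119) were called, as were G2/M genes, NF-kB targets and sterol synthesis genes (0.00339, 0.0124 and 0.00339).

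The differences between the lines recurred under both treatments. CTSD, HOXB2, MUC5AC, MUC1 and BRINP3 were among 76 genes higher in both, against 1.36 expected for independent lists of 167 and 105. NCAM2, UGT1A6, DSCAM, CAV1 and MALRD1 were among 167 lower in both, against 4.84 expected for lists of 256 and 243. No gene was called in opposite directions: 0 of the 243 shared genes, by edgeR. The shared count was 151 and 155 without NCS-treated GFP replicates 1 and 2, 138 and 151 without NCS-treated MYC-GFP replicates 1 and 2, and 161 without untreated MYC-GFP replicate 1. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.766.

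The last comparison asked whether NCS changed genes differently in the MYC-GFP line. No gene passed the threshold: edgeR called 0 on both scales, with 179 genes relative to the typical gene and 103 per S. pombe read at an unadjusted p under 0.05, and DESeq2 and limma called 0, while edgeR called 2 relative to the typical gene in the fit without replicate 3 of each group. CDKN1A, the p21 gene, differed by -0.63 on the log2 scale (standard error 0.32, edgeR adjusted p = 1, n = 3 per group) and AURKA by 0.41 (standard error 0.24, edgeR adjusted p = 1), neither past the threshold. As a list, immediate early genes changed less upwards in the MYC-GFP line, with a median log2 difference of -0.52 (25 of 25 genes negative, camera adjusted p = 4.61e-12). p53 targets had a median of -0.24 (34 of 48 negative, camera adjusted p = 0.000132), G2/M genes 0.20 (33 of 38 positive, 0.000987) and luminal genes -0.17 (14 of 18 negative, 0.00849). All 4 calls were lost, with adjusted p = 0.139, 0.101, 0.101 and 0.446 with an estimated correlation, and the luminal call also ended without untreated GFP replicate 2 (0.0664), NCS-treated GFP replicate 2 (0.0521), untreated MYC-GFP replicate 3 (0.103) or NCS-treated MYC-GFP replicate 1 (0.0524).

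**Figure D3:**
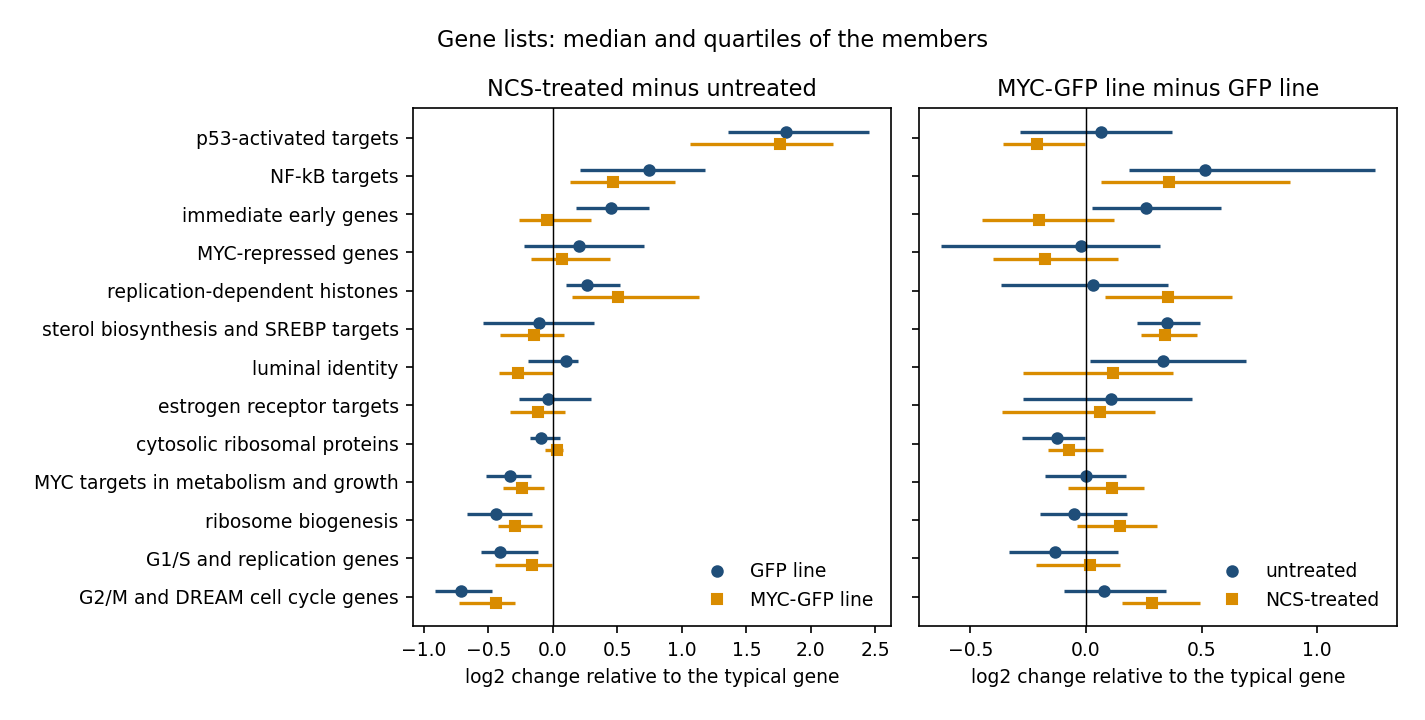
Median log2 changes of gene lists relative to the typical gene, for NCS in each line and for the lines compared under each treatment. p53 targets stood at 1.81 and 1.76 after NCS in the GFP and MYC-GFP lines and G2/M genes at -0.71 and -0.44.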

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

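The counts over other splits of the samples were chosen only after these results were seen. By camera at its preset correlation, 4 gene lists differed in their NCS change between the 2 lines, but 0 did with an estimated correlation or by fry. edgeR called 0 single genes for that difference on both scales (179 and 103 at an unadjusted p under 0.05, 0 by DESeq2 and limma, and 2 by edgeR without replicate 3 of each group, relative to the typical gene). Immediate early genes, which answer growth and stress signals within minutes, had a median log2 difference (MYC-GFP line minus GFP line) of -0.52, with EGR3 at -1.50, JUND at -0.79, CTGF at -0.66 and KLF4 at -0.52 and 25 of 25 genes negative. Targets of p53 differed by -0.24 (CDKN1A -0.63, SUSD6 -0.74), G2/M genes by 0.20 (CENPE 0.86, AURKA 0.41) and luminal genes by -0.17 (XBP1 -0.52). With n = 3 libraries per group, the camera adjusted p values were 4.61e-12, 0.000132, 0.000987 and 0.00849 at the preset correlation, and all 4 calls were lost with an estimated correlation, at 0.139, 0.101, 0.101 and 0.446. By fry the adjusted p values were 0.316, 0.182, 0.182 and 0.663.

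For the immediate early genes a single library was weighed as a source. Without replicate 3 of the untreated GFP line the median was smaller but kept its sign (-0.36, against -0.52 with all libraries). The camera adjusted p was 0.000129, the highest of a range from 2.86e-15. It is at the preset correlation, at which lists were also called in 95 of the other splits of the libraries. It therefore cannot show whether a difference remained without that library. The range was 2.36e-05 to 0.0251 for p53 targets and 0.000433 to 0.0426 for G2/M genes, and the luminal call ended without untreated GFP replicate 2 (0.0664), NCS-treated GFP replicate 2 (0.0521), untreated MYC-GFP replicate 3 (0.103) or NCS-treated MYC-GFP replicate 1 (0.0524). Of 100 splits of the libraries within each group pair, 39 gave at least the real 4 lists, the highest other giving 11, so chance cannot be excluded for the number of lists.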

How the results depend on the processing

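Alternatives without 3 libraries, each the highest of its group in short-transcript share (replicate 3 of untreated GFP, untreated MYC-GFP and NCS-treated MYC-GFP), without replicate 3 of each group, without p53 targets among MYC-repressed genes, of shared genes in fits of 2 groups, by length quartile, by matched length and on reads per kilobase were chosen after seeing the data, and the others were planned. Of results that answer a comparison, 160 values over alternatives and 141 over fits leaving out 1 library stayed the same. For counts this means within 1.5 times the main count, and for the ratio to S. pombe reads the same sign and side of 0.05. Of the rest, 45 and 47 counts moved by more, 5 and 0 ratios lost a call, 3 and 2 gained one and 2 and 2 changed sign. For a ratio between 2 groups the side of 0.05 was fixed in advance, since 3 against 3 libraries or fewer cannot pass it. Single genes include some not called in the main fit, which had no call to lose. Of single genes, 993 over alternatives and 669 over fits leaving out 1 library kept sign and call, while 56 and 156 lost a call, 10 and 2 gained one and 8 and 7 changed sign. Of lists 139 and 185 did, 38 and 13 lost a call and 1 turned: histones after NCS in GFP without replicate 3 of each group (camera adjusted p = 0.787, median -0.21). Except where the construction shows it (fewer libraries or genes, another threshold), the cause was not tested. The NCS change in human reads per S. pombe read over both lines lost its call for short transcripts (-0.55, exact permutation p = 0.06), for long ones (-0.19, 0.06) and without the 3 libraries (-0.26, 0.0833) or replicate 3 of each group (-0.22, 0.167). That of the lines gained one with the deposited scores (0.27, exact permutation p = 0.02) and for long transcripts (0.32, 0.015), and the interaction turned to -0.040 with the scores and -0.022 without replicate 3 of each group. Leaving out each library gave -0.61 to -0.29 for NCS in GFP cells, -0.54 to -0.21 in MYC-GFP cells, -0.49 to -0.33 over both, 0.06 to 0.40 for the lines untreated, 0.23 to 0.37 with NCS, 0.18 to 0.35 over both (0.35 without untreated GFP replicate 3 or untreated MYC-GFP replicate 2, where a call was gained) and -0.090 to 0.24 for the interaction (-0.080 without untreated GFP replicate 3, -0.090 without untreated MYC-GFP replicate 2). Called genes relative to the typical gene (NCS in GFP, NCS in MYC-GFP, lines untreated, lines with NCS) were 297, 179, 714 and 599 by DESeq2 and, in fits of 2 groups, 70 (GFP), 134 and 557 (lines). They ranged over 90 to 253, 51 to 64, 212 to 485 and 162 to 234 without each library, and 0 to 0 for the interaction on both scales. Per S. pombe read, DESeq2 gave 990, 168, 728 and 773 (916 of the 990 lower, with 3991 genes given no adjusted p), the scores 113 (NCS in GFP) and 503 (lines untreated), and no filter 119 (NCS in GFP). limma on reads per kilobase over the scores stands for the planned spike-in normalised table, which holds no such scaling: 118, 72 and 522 with pseudocount 1, 69 (NCS in MYC-GFP) with 0.1, and 143 and 75 (NCS) unscaled. Without each library the ranges were 31 to 3199, 17 to 30, 154 to 347 and 120 to 188. Without the 3 libraries, counts were 782 (relative) and 869 (per S. pombe read) for the lines with NCS, 174 for NCS in GFP per S. pombe read, and 8 (lines with NCS) and 7 (interaction) lists. Without replicate 3 of each group they were 366, 208, 840 and 2361 (relative) with 2 for the interaction, 1268 per S. pombe read for the lines with NCS, 8 lists for the lines with NCS, and 415 genes shared between the line contrasts. In that fit the NCS-treated lines also differed in short-transcript share (25.5 and 27.3% for GFP, 20.4 and 20.8% for MYC-GFP). MYC-repressed genes without p53 targets gave camera adjusted p = 0.536 and 0.857 for NCS in the GFP and MYC-GFP lines. Called lists were 4, 0, 0 and 0 with an estimated correlation (NCS in MYC-GFP, lines untreated, lines with NCS, interaction) and 5, 7 and 0 by fry (NCS in MYC-GFP, lines with NCS, interaction), and 9 to 10, 7 to 12, 4 to 6, 3 to 8 and 4 to 7 without each library. Shared genes were 120 (lines) in fits of 2 groups, 48 (NCS) and 122 (lines) at adjusted p under 0.01, 137 and 388 by DESeq2, and 48 to 87 and 138 to 291 without each library. Signs of uncalled genes turned for MDM2 between untreated lines (-0.016 at a mean of at least 5 CPM, -0.084 and -0.085 without the 3 libraries or replicate 3 of each group, -0.39, -0.30 and -0.016 without untreated GFP replicate 3 and MYC-GFP replicates 1 and 2, from -0.39 to 0.64 without each library), for MDM2 between lines with NCS (-0.056 and -0.050 without GFP and MYC-GFP replicate 2, up to 0.39), for TP53 after NCS in GFP (-0.25 without untreated replicate 3 or the 3 libraries, -0.24 without replicate 3 of each group, up to 0.48) and for MYC between untreated lines (-0.060 without GFP replicate 3, -0.057 without the 3 libraries and -0.059 without replicate 3 of each group, up to 0.36). The numbers were not taken to pair libraries over all groups: same-numbered deviations correlated with r from -0.559 to 0.508, 8 of 18 above 0.1, and 5 of 12 libraries correlated best with their own number. With a replicate block the NCS change over both lines had p = 0.0625 (log2 -0.41, exact permutation), that between lines p = 0.0313 (0.27, exact permutation) and MDM2 between lines with NCS was -0.056, and no count of calls moved by over 1.5 times. Genes of few reads limit what these depths show, as the floor of 3 counts gives.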

Other observations

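The test of chromosome windows, the reading of MYC target lists against MYC activity, the relation of the short-transcript share to human reads per S. pombe read and all counts over other splits were chosen only after the results were seen. The tests by length quartile and of the S. pombe short-transcript share were not planned either, and were added once a difference in transcript length between libraries had been seen. Genes in this paragraph were chosen after their values were seen. Some of the genes that differed between the untreated lines lay close together. They are shown for the windows lowest and highest by the mean of their medians in untreated and NCS-treated cells. Whether called genes cluster in general was not tested. On chromosome 19, from 37288452 to 38899728, 10 of 25 genes were lower in the MYC-GFP line, among them the zinc finger genes ZNF420 (log2 -2.51) and ZNF585A (-1.92), and from 44235301 to 45496604 another 9 of 25 were lower, among them ZNF223 (-3.80), ZNF229 (-3.87) and ZNF233 (-2.86). Zinc finger genes of such clusters resemble each other, so the split of reads among them is uncertain. On chromosome 11, from 790475 to 2418649, 6 of 25 genes were higher, among them CTSD (2.77), the interferon-induced membrane gene family member IFITM10 (2.75), the imprinted RNA H19 (2.37) and the mucin gene MUC5AC. Further along, from 94898677 to 107729914, 4 of 25 were higher and 1 lower. The progesterone receptor gene PGR (2.03, edgeR adjusted p = 0.0136) was higher, though not without GFP replicate 1 (0.0627) or MYC-GFP replicate 2 (0.0753). The collagenase gene MMP13 was lower (-3.15, 0.0387), though not without any library other than GFP replicate 3 (0.0533 to 0.154). On chromosome 2, from 38790328 to 45236542, 3 of 25 were higher (window median 0.60, and 0.69 with NCS). At the start of chromosome 1 (14362 to 1310818) the median gene was -0.95. There HES4 (-1.19) and the ubiquitin-like ISG15 (-2.43) were called, but HES4 not without any library other than GFP replicate 2 (edgeR adjusted p 0.088 to 0.165), and ISG15 not without GFP replicate 3 (log2 -1.57, 0.0562) or any 1 MYC-GFP replicate (0.0759 to 0.101). With NCS the medians of the other 5 windows were -1.19, -0.97, 0.67, 0.80 (0.795) and -0.98. The windows were picked on both treatments, so these medians are no separate sign of recurrence.

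CXCL8, an NF-kB target that encodes a neutrophil chemokine, had 0 reads in the untreated GFP line and 25 in the untreated MYC-GFP line, at least 8.49-fold higher, and 12 in the NCS-treated GFP line, at least 5.19-fold higher. These reads are sums over the libraries of a group. The bounds cover counting error of the 0 only, not that of the 25 and 12 or the spread between libraries. CXCL8 was named outside the rule for genes. With CXCL8 at its bound the medians of the NF-kB list stayed at 0.517 and 0.746.

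Differences between the lines may come in part from the 2 being separate clones, whose chromosomes can differ in segments. Medians of 498 windows of 25 genes spread 2.21 times as widely as in random gene orders for the untreated lines and 2.42 times with NCS (each p = 0.001, the smallest that 1000 orders give), and the medians of both contrasts correlated across windows with r = 0.879. The NCS contrasts, which compare cells of 1 clone, spread 1.78 and 1.73 times (p = 0.001) with r = 0.822, so neighbouring genes also move together without a clonal difference. What part of the spread between the lines is clonal cannot be told from these values. Higher MYC activity stays open as well: neither MYC target list was called by camera in either contrast (smallest camera adjusted p = 0.121), while by fry ribosome biogenesis was called with NCS (adjusted p = 0.0412, 27 of 40 positive, median 0.15 and 0.41 per S. pombe read). MYC RNA was not called higher, and MYC protein was not measured.

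Replicate libraries of 1 group differed in human reads per S. pombe read, from 57.7 to 90.3 in the untreated GFP line and from 66.6 to 105 in the untreated MYC-GFP line. A length bias of whole libraries was tested through the shares of reads from short transcripts. Within groups, over 12 libraries, the human and S. pombe shares correlated with r = 0.93 (exact permutation p = 0.000772, the smallest of 1296 arrangements) and rho = 0.902 (exact permutation p = 0.000772), r = 0.918 without the 2 farthest, Benjamini-Hochberg value 0.00154 over 2 relations. The human share also correlated with human reads per S. pombe read, r = 0.709 (exact permutation p = 0.0193) and rho = 0.755 (exact permutation p = 0.0108), r = 0.622 without the 2 farthest, Benjamini-Hochberg value 0.0193. Both a length bias and carryover of short unlabelled human RNA may thus contribute, since carryover alone would not move the S. pombe reads.

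The lower human reads per S. pombe read after NCS could reflect less transcription per cell or less carryover of short RNA, and these data leave both open. The longest quartile of transcripts fell by 0.188 on the log2 scale and the shortest by 0.55, with the larger exact permutation p of the pair at 0.06. Carryover of short RNA would leave the long transcripts in place, and their change of -0.188 did not pass 0.05 (exact permutation p = 0.06). A shared error in cell counts was not testable here. A length bias of whole libraries, weighed above for the replicates, was not tested as a source of this change.

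Other splits of the same libraries were fitted for each count. For the shared genes each contrast was fitted on its 2 groups alone, which gave 54 shared genes for NCS and 120 for the lines. Of 100 splits only the real 1 gave as many, with 0 as the highest other. This decides nothing about chance, since in all other splits but 1 a switched contrast had 0 calls and so shared 0. In that 1 the line contrasts had 134 and 2390 calls and shared 0. The 2390 came from the exchange of replicate 3 between the NCS-treated lines. It set short-transcript shares of 25.5, 27.3 and 27.0% against 20.4, 20.4 and 20.8%. In the fit of 4 groups (75 and 243, highest other 0) a switch in 1 contrast also took the calls of the untouched contrast to 0, so its splits decide nothing either. For the 4 pairwise contrasts 10 splits are too few for a share under 0.05. The real counts after NCS were 157 and 87 relative to the typical gene and 72 and 45 per S. pombe read, with 0 as the highest other. Between the lines with NCS they were 348 and 316 with 0 as the highest other. These are counts from the fit of 4 groups. Fitted on their 2 groups alone, the lines with NCS gave 557 calls relative to the typical gene, fewer than the 2390 of the exchange of replicate 3. The other contrasts gave no calls in any other split when fitted that way. Between the untreated lines the real counts were 423 and 334 and the highest other 604 and 1101. Those came from the exchange of untreated GFP replicate 2 with untreated MYC-GFP replicate 3. That exchange set long-transcript shares of 26.3, 19.5 and 22.1% against 28.1, 27.1 and 31.3%, while the short-transcript shares overlapped. For the interaction all 100 splits gave at least the real 0, and 1 gave 1557 and 257. There the groups standing for GFP, GFP NCS, MYC-GFP and MYC-GFP NCS differed in short-transcript share. The shares were 20.4 to 24.2%, 25.5 to 35.3%, 25.1 to 27.5% and 20.4 to 23.6%. The interaction sets the first and last of these against the other 2. When the lines were split within treatments instead, 1 gave 1951 and 239 and another 0 and 637. In the split with 1951 the shares were 21.3 to 24.2%, 25.5 to 27.3%, 25.1 to 35.3% and 20.4 to 20.8% in the same order. Large counts in other splits thus went with transcript length in the libraries, and whether length caused them was not tested. For the lists the real numbers were 9, 9, 4 and 3, with 9, 9, 6 and 7 as the highest others and 6, 6, 4 and 4 as the medians of the others. Of 10 splits, the real one included, 2, 2, 6 and 7 gave at least the real number. The lists called between the lines were thus no more numerous than in other splits.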
